A study of Arabidopsis thaliana with 12 samples.

How the data were processed

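RNA was sequenced from 12 libraries of whole Arabidopsis thaliana plants, 2 weeks old, in 4 groups of 3 that the series design calls biological replicates. The labels give the genotype (Col-0 or the rdd mutant) and the soil (regular, called control here, or with YC4-R4), and libraries were grouped by these labels alone. Per the labels' protocols, RNA was extracted with RNeasy columns and 1 µg was made into libraries with the NEBNext Ultra Directional kit. The deposited values are whole-number read counts per gene, 1 column per library. Per the submitters' processing notes, the tools named were Trimmomatic 0.36, HISAT2 2.1.0 and HTSeq 0.9.1, and the genome build was TAIR10. The strand setting of the counting and the annotation release are not given in the sources used here. Genes that overlap another gene, and copies that share reads, are therefore uncertain. Of the 183 genes named by the rule given here, 39 overlap another annotated gene and 33 another tested gene. Not all are marked where they are named. Among list members, SARD1, WRKY40, WRKY53, P5CS1, LHCB3, PYK10, APR1 and RCA also overlap another tested gene.

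The table held 33602 genes, of which 6493 had no count in any library and 32835 matched a gene of the reference annotation used here, TAIR10.1. Symbols, descriptions and coordinates come from that annotation, as the count table carries none. Library totals ran from 14465710 to 20281801 counts. Genes of the chloroplast and mitochondrion took 0.950% to 1.36% of a library, and the 10 most counted genes 5.97% to 7.66%. No pair of replicates differed by counting noise alone. Over genes with at least 50 counts in a pair, chi-square per degree of freedom ran from 1.61 to 2.28 in 3 groups and from 3.40 to 5.45 in the libraries labelled rdd YC4-R4.

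Counts were analysed as deposited, in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 20651 genes, 20505 of them with a reference entry and together holding 99.96% of the counts. TMM factors were 0.941 to 0.954 in the libraries labelled Col-0 control and 1.00 to 1.04 in the others. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which left 8 residual degrees of freedom. The 5 comparisons were YC4-R4 against control in Col-0 and in rdd, rdd against Col-0 in control and in YC4-R4 libraries, and the genotype by treatment interaction, which is the YC4-R4 effect in rdd minus that in Col-0. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, with no fold threshold. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-normalized CPM, and the log2 CPM used for gene lists had a prior count of 2. A fold against a group with 0 counts was taken against a floor of 3 counts over the group. A ratio with 1 to 3 counts was given a 95% interval, which covers counting error only.

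The test was tested on simulated data drawn from the real means and library sizes, with 20514 genes run and 50 genes changed per fold. For YC4-R4 against control in Col-0 it recovered 48% of genes changed 1.2-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 0.0490% of unchanged genes. For the interaction these shares were 20%, 66%, 96% and 100%, with 0.0930% of unchanged genes called. Changed genes had an average log2 CPM of 1 or more, and each gene had 1 spread for all groups. Far fewer genes changed there than were called in the real data, so these shares need not hold for it.

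Before the data were examined, the design, the alternatives, the rule for named genes and 24 gene lists with 420 entries were fixed. The lists were the mutated demethylases, DNA methylation and demethylation machinery, methylation-sensitive loci, myo-inositol, salicylic acid, pattern-triggered immunity, camalexin, jasmonate, jasmonate-ethylene defence, photosynthesis, auxin response, cell wall expansion, iron deficiency, phosphate starvation, sulfur deficiency, aliphatic glucosinolates, flavonoids, abscisic acid with drought and cold, heat shock, morning clock, evening clock, senescence, root markers and floral organ markers. The 23 lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. They were tested again with an estimated correlation and with fry. The rule named the 10 highest and 10 lowest fold changes among called genes with an average log2 CPM of 1 or more and, except in the interaction, no overlap between the libraries compared. It also named the 4 members with the smallest adjusted p of each called list and of the myo-inositol, salicylic acid, pattern-triggered immunity, jasmonate and photosynthesis lists. ROS1, DML2 and DML3 were named in each comparison, and MIPS1, MIPS2 and MIPS3 in the YC4-R4 comparisons. A list of 12 genes of the rapid response to touch and wounding was written after the counts were at hand and before its values were seen.

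The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit to the 6 libraries of a pairwise comparison alone, the replicate number as a block, a 2-fold threshold, an adjusted p under 0.01, library sizes without organelle genes, and leaving out each library in turn. DNA methylation was not analysed here.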

Results

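Messenger RNA was sequenced from whole 2-week-old Arabidopsis thaliana plants grown in soil. The labels describe Col-0, the reference accession, and rdd, a mutant of the DNA demethylase genes ROS1, DML2 and DML3, whose enzymes excise methylated cytosine from DNA. Plants of each genotype were grown in regular soil (control) or in soil with YC4-R4. The series title speaks of beneficial root bacteria and of myo-inositol, and the design asks how the response to YC4-R4 differs between plants with and without these demethylases. The 4 groups hold 3 libraries each, which the series design calls biological replicates. Gene counts per library summed to between 14465710 and 20281801, and 20651 genes were tested. The biological coefficient of variation was 3.05% in the libraries labelled Col-0 control, 2.57% in Col-0 YC4-R4, 3.22% in rdd control and 5.84% in rdd YC4-R4. The p-values measure changes against this spread within groups. A difference in growth or harvest shared by all libraries of a group cannot be told apart from treatment or genotype. Errors after a log2 fold change are standard errors, and levels are CPM, counts scaled to a common library total, given as mean ± SD with n = 3.

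The mutated genes did not follow the genotype labels. DML3 (AT4G34060, chromosome 4, 16313366 to 16319426 in TAIR10.1) stood at 4.97 ± 0.79 CPM in the libraries labelled Col-0 control and 3.52 ± 0.14 CPM in those labelled rdd control. It stood at 0.775 ± 0.403 CPM in Col-0 YC4-R4 and 0.599 ± 0.343 CPM in rdd YC4-R4. DML2 (AT3G10010, chromosome 3, 3081735 to 3088550) showed the same split, at 19.9 ± 0.42 and 20.7 ± 2.11 CPM in the libraries labelled control and 13.0 ± 1.38 and 13.5 ± 0.43 CPM in those labelled YC4-R4. ROS1 (AT2G36490, chromosome 2, 15307907 to 15314807) stood at 81.9 ± 3.94 CPM in Col-0 control, 69.5 ± 1.58 in Col-0 YC4-R4, 79.9 ± 2.23 in rdd control and 74.5 ± 1.68 in rdd YC4-R4. With YC4-R4, DML3 fell by 2.63 ± 0.27 on the log2 scale in the libraries labelled Col-0 and by 2.57 ± 0.29 in those labelled rdd (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.8e-10 and 6.5e-09). DML2 fell by 0.62 ± 0.09 and 0.61 ± 0.09 (edgeR, Benjamini-Hochberg adjusted p = 5.1e-07 and 4.6e-07). Between rdd and Col-0, DML2 differed by 0.05 ± 0.08 in control and 0.06 ± 0.09 in YC4-R4 libraries (edgeR, Benjamini-Hochberg adjusted p = 0.665 and 0.670). ROS1 was lower with YC4-R4 in the libraries labelled Col-0 (-0.24 ± 0.05) and differed by -0.10 ± 0.05 in those labelled rdd (edgeR, Benjamini-Hochberg adjusted p = 9.4e-05 and 0.0950). DML3 was lower in rdd than in Col-0 control libraries by a smaller amount (-0.50 ± 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.0431). This call was lost with DESeq2 (adjusted p = 0.109), with the replicate number as a block (0.0538), without Col-0 control replicate 2 (0.227) and without rdd control replicate 1, 2 or 3 (0.0932, 0.0706 and 0.0954), and its edgeR or DESeq2 adjusted p ran from 0.0418 to 0.227 over the alternatives. The fourth family member DME, which the labels do not name as mutated, stood at 74.2 ± 4.50, 71.2 ± 2.40, 83.5 ± 2.35 and 69.7 ± 4.11 CPM in the same order of groups. A count over the whole gene need not fall where an insertion leaves part of the transcript. These counts therefore do not bear out the genotype labels, but cannot show them to be wrong. Each direction below is drawn between libraries as labelled.

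**Figure D1:**
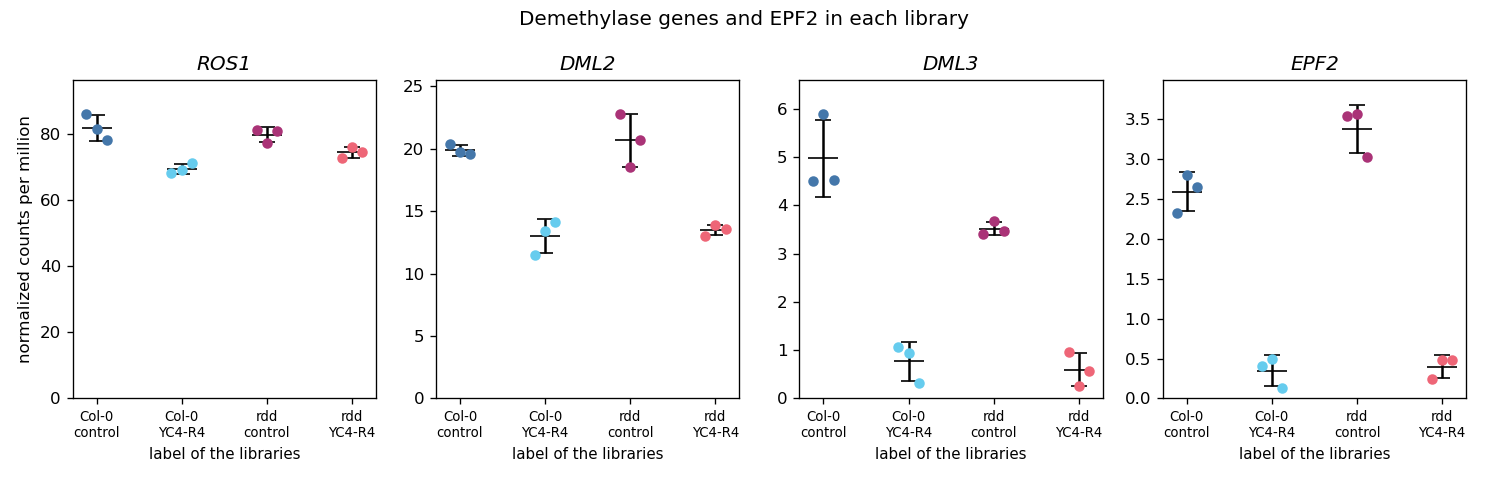
Normalized CPM of ROS1, DML2, DML3 and EPF2 (vertical axis, from 0) in each of the 12 libraries by label (horizontal axis); points are libraries, the horizontal bar is the mean and the whiskers are 1 SD (n = 3). DML3 means were 4.97 and 3.52 CPM in the libraries labelled control and 0.775 and 0.599 CPM in those labelled YC4-R4.

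In the libraries labelled Col-0, WRKY33 and WRKY70 were lower with YC4-R4, and CYP94C1 and CYP94B1 were higher. WRKY33, a transcription factor of pathogen responses, went from 246 ± 10.7 CPM in control to 29.5 ± 2.87 CPM with YC4-R4 (log2 -3.07 ± 0.07). WRKY70, a regulator in salicylic acid signalling, fell by 2.24 ± 0.06. CYP94C1, which inactivates jasmonoyl-isoleucine by oxidation, rose from 8.97 ± 0.44 to 41.2 ± 1.18 CPM (log2 2.2 ± 0.08), and CYP94B1 of the same family rose by 2.67 ± 0.17 log2 units. CYP94B3, a further member, picked out here after its values were seen, was lower, at 21.9 ± 0.38 CPM in control and 16.1 ± 0.78 CPM with YC4-R4 (log2 -0.45 ± 0.08; edgeR, Benjamini-Hochberg adjusted p = 7.3e-05). Among the genes with the highest fold changes were also CPK22, annotated as like a calcium-dependent kinase (4.62 ± 0.23), the 2-oxoglutarate-dependent oxygenase AT2G38240 (3.74 ± 0.29), RBL7 (2.87 ± 0.26), the AP2/ERF-type factor ABR1 (2.75 ± 0.20) and the terpene synthase TPS04 (2.34 ± 0.20). Among those with the lowest were MRD1 (-7.24 ± 0.17; -8.24 without Col-0 YC4-R4 replicate 2), the receptor-like kinase CRK40 (-5.50 ± 0.10), the ethylene synthesis enzyme ACS11 (-5.05 ± 0.20), the starch-related orphan gene QQS (-4.80 ± 0.31), AT1G35210 (-4.73 ± 0.18) and AT2G33830, annotated as dormancy or auxin associated (-3.79 ± 0.06). The pseudogene AT4G17450 had 764 counts over the control libraries and 0 over the YC4-R4 libraries, which puts it at least 244-fold lower, against a floor of 3 counts over the group. Apart from CYP94B3, the highest adjusted p among these genes was 3.0e-11, for RBL7 (edgeR, Benjamini-Hochberg). MRD1, RBL7, ABR1 and WRKY33 overlap another tested gene in the annotation, and their counts are uncertain to that extent.

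By list, 12 of 21 pattern-triggered immunity genes were lower and 3 higher in that comparison, or 13 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.5e-06; adjusted p = 0.0557 with an estimated correlation). Among them were WRKY33, MYB51 (-2.03 ± 0.07), WRKY40 (-2.00 ± 0.07) and the oxidase RBOHD (-1.03 ± 0.05). The list of 12 genes of the rapid response to touch and wounding moved with them, 11 lower and 0 higher, with a median of -1.95 (camera p = 1.3e-15, not adjusted for other lists; p = 0.00530 with an estimated correlation). The libraries labelled Col-0 control stood apart from the other groups for WRKY33 (246 CPM against 29.1 to 43.9) and WRKY70 (218 CPM against 39.4 to 48.3). Of 30 salicylic acid genes, 10 were lower and 4 higher, or 11 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0484; adjusted p = 0.122 with an estimated correlation). WRKY53 was at -1.89 ± 0.08 and CBP60G at -1.71 ± 0.07. Members that were higher included PR2 (5.82 ± 0.48 to 22.0 ± 1.83 CPM) and PR5 (3.87 ± 0.94 to 11.9 ± 0.56 CPM), picked out after their values were seen. The salicylic acid call was also lost with the replicate block (0.0665) and without Col-0 control replicate 1 or 3 (0.0895 and 0.0718) or Col-0 YC4-R4 replicate 1 (0.0701), with a range of 0.0265 to 0.122 over the camera alternatives. The fry test, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, gave an adjusted p of 8.7e-07. Of 29 jasmonate genes, 16 were higher and 6 lower, or 18 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.2e-06; adjusted p = 0.0326 with an estimated correlation). The synthesis genes AOC1 (1.37 ± 0.06), AOC2 (0.90 ± 0.04) and OPR3 (0.87 ± 0.04) rose, AOC1 and AOC2 being similar copies whose counts are uncertain. Photosynthesis genes were lower in 38 of 40 cases by small amounts, median -0.31, and in 38 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.0e-17; adjusted p = 0.0682 with an estimated correlation). Examples were LHCB1.4 (-0.84 ± 0.04) and LHCB2.1 (-0.67 ± 0.05), members of families of near-identical copies. Aliphatic glucosinolate genes were higher in 10 and lower in 3 of 15 cases, or 11 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00283; adjusted p = 0.0579 with an estimated correlation). MAM1 was at 0.62 ± 0.04 and CYP79F2 at -0.62 ± 0.07. The 5 morning clock genes were all lower, also adjusted over the list alone, with a median of -0.78 (camera, Benjamini-Hochberg adjusted p = 5.5e-05; adjusted p = 0.0595 with an estimated correlation). CCA1 was at -0.78 ± 0.07 and LHY at -1.09 ± 0.09. The 3 mutated demethylases were called as a list, all lower, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0119; adjusted p = 0.0682 with an estimated correlation). Root markers were higher in 2 and lower in 2 of 18 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.619). Over all genes, 2661 were higher and 3484 lower with YC4-R4 (edgeR, Benjamini-Hochberg adjusted p under 0.05), with a median absolute log2 fold change of 0.33, and 682 of them changed 2-fold or more, 204 higher and 478 lower.

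In the libraries labelled rdd, CYP94C1 and FLS2 were lower with YC4-R4, and PR2 and CHS were higher. CYP94C1 fell from 49.5 ± 3.28 CPM in control to 4.03 ± 0.60 CPM (log2 -3.61 ± 0.09), opposite to its direction in Col-0. The pathogenesis-related glucanase gene PR2 rose from 4.51 ± 1.08 to 27.9 ± 4.65 CPM (2.65 ± 0.12), and it was also higher with YC4-R4 in Col-0 (5.82 ± 0.48 to 22.0 ± 1.83 CPM). CHS, which encodes the entry enzyme of flavonoid synthesis, rose by 1.24 ± 0.07 log2 units, and the flagellin receptor gene FLS2 fell by 1.01 ± 0.06. Other genes with the highest fold changes were the pseudogene AT5G35935 (4.12 ± 0.17), CPK22 (3.84 ± 0.21), the cellulose synthase-like gene CSLA01 (3.38 ± 0.16), the iron-uptake peptide gene IMA3 (2.66 ± 0.18) and AT2G15020 (2.62 ± 0.21). The lowest included MRD1 (-6.75 ± 0.14), AT3G47965 (-6.07 ± 0.34; -6.74 without rdd YC4-R4 replicate 2), CRK40 (-4.49 ± 0.09), AT1G08940 (-4.21 ± 0.27), ACS11 (-4.16 ± 0.25) and QQS (-4.12 ± 0.31). AT4G17450 had 746 counts over the control and 1 count over the YC4-R4 libraries, a ratio of 810 with a 95% counting interval of 145 to 32030. The highest adjusted p among these genes was 2.1e-12, for AT2G15020 (edgeR, Benjamini-Hochberg). AT5G36790, with a close copy in the genome, rested on 1 library: it was higher by 2.67 ± 0.49 (edgeR, Benjamini-Hochberg adjusted p = 3.9e-05). It was at 54.5 CPM in rdd YC4-R4 replicate 2 against 6.72 and 6.44 CPM in the other libraries of that group. Without that library it was higher by 0.89 (edgeR, Benjamini-Hochberg adjusted p = 7.2e-04). IMA3, CHS and FLS2 overlap another annotated gene.

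By list, 16 of 29 jasmonate genes were lower and 6 higher with YC4-R4 in the libraries labelled rdd, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.5e-04; adjusted p = 0.0295 with an estimated correlation). The repressor gene JAZ6 fell by 1.2 ± 0.05 while LOX2 (1.04 ± 0.04) and CORI3 (1.56 ± 0.05) rose. Pattern-triggered immunity genes were lower in 15 and higher in 0 of 21 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.1e-08; adjusted p = 0.0157 with an estimated correlation). PHI1 was at -2.63 ± 0.07, WRKY40 at -1.60 ± 0.08 and WRKY22 at -1.2 ± 0.07. In the touch and wounding list, 10 of 12 genes were lower and 0 higher, with a median of -0.64 (camera p = 3.1e-07, not adjusted for other lists; p = 0.0415 with an estimated correlation). Salicylic acid genes went both ways, 13 higher and 8 lower of 30, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.447). PR5 was at 1.49 ± 0.13, WRKY54 at 0.73 ± 0.09 and NPR3 at -0.58 ± 0.05. Flavonoid genes were higher in 7 and lower in 0 of 14 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.6e-05; adjusted p = 0.0157 with an estimated correlation). Among them were FLS1 (1.18 ± 0.11) and CHI (1.11 ± 0.16). Cell wall expansion genes were higher in 8 and lower in 3 of 11 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00688; adjusted p = 0.0477 with an estimated correlation). EXPA1 was at 1.27 ± 0.04 and EXPA10 at 1.21 ± 0.06, while the touch-inducible TCH4 fell by 1.92 ± 0.04. Sulfur deficiency genes were higher in 7 and lower in 2 of 13 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0329; adjusted p = 0.149 with an estimated correlation). LSU1 was at 1.57 ± 0.24. Evening clock genes were lower in 4 and higher in 1 of 6 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0329; adjusted p = 0.231 with an estimated correlation). PRR5 was at -0.74 ± 0.05 and GI at -0.70 ± 0.06. Root markers were lower in 8 and higher in 0 of 18 cases, or 9 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00242; adjusted p = 0.0295 with an estimated correlation). MRN1 was at -0.83 ± 0.16 and THAD1 at -0.53 ± 0.08.

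Of the 5 tested loci known to change with DNA methylation, 3 were lower and 0 higher with YC4-R4 in the libraries labelled rdd, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0485; adjusted p = 0.215 with an estimated correlation). QQS, also in this list, fell by 4.12 ± 0.31 (edgeR, Benjamini-Hochberg adjusted p = 1.9e-13). EPF2, a peptide gene of stomatal patterning, fell by 3.03 ± 0.29 and the allantoinase gene ALN by 0.15 ± 0.06 (edgeR, Benjamini-Hochberg adjusted p = 1.3e-10 and 0.0422). With YC4-R4 in Col-0, QQS was at -4.80 and EPF2 at -2.86, in a list with 2 higher and 2 lower (camera, Benjamini-Hochberg adjusted p = 0.823). The ALN call was lost with DESeq2 (0.0954) and without any of 4 libraries, rdd control replicate 1 or 3 (0.0886 and 0.168) or rdd YC4-R4 replicate 1 or 3 (0.0715 and 0.262), with a range of 0.00697 to 0.262 over the alternatives. The demethylases were lower in 2 of 3 cases, or 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0388; adjusted p = 0.143 with an estimated correlation). Without rdd control replicate 3 or rdd YC4-R4 replicate 3, the methylation locus call (0.104 and 0.0749) and the demethylase call (0.0601 and 0.0555) were lost. Over the camera alternatives these ran from 0.0362 to 0.215 and from 0.0361 to 0.143, and fry, against no change, gave 6.0e-05 and 1.4e-05. Photosynthesis genes were lower in 20 and higher in 6 of 40 cases, or 22 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0761). LHCB1.2 was at -0.41 ± 0.04 and LHCB4.3 at 0.85 ± 0.06. Morning clock genes were higher in 2 of 5 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.272). In total 3120 genes were higher and 3532 lower with YC4-R4 (edgeR, Benjamini-Hochberg adjusted p under 0.05), with a median absolute log2 fold change of 0.34, and 658 of them changed 2-fold or more, 178 higher and 480 lower. The libraries labelled rdd YC4-R4 spread more than the other groups, with a coefficient of variation of 5.84%.

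Some changes with YC4-R4 were shared between the libraries labelled Col-0 and rdd, and others went in opposite directions. Genes called in both numbered 3139, of which 498 were higher in both (402 for independent lists), 1137 lower in both (596 for independent lists) and 1504 went in opposite directions (981 for independent lists). For rdd against Col-0 in control and YC4-R4 libraries, 3772 genes were called in both, of which 1265 were higher in both (618 for independent lists), 1496 lower in both (684 for independent lists) and 1011 went in opposite directions (1302 for independent lists). Called changes of 8-fold or more with YC4-R4 numbered 53 in Col-0 and 43 in rdd, and were in the same direction in both for 26 genes, 4 higher and 22 lower, or 25 with groups at 0 counts set to the floor of 3. MRD1, CRK40, ACS11, QQS, CPK22 and AT2G33830 were among them. AT2G38240, higher by 3.74 in Col-0, was not: it went from 5.19 to 1.02 CPM in rdd. Between the rdd against Col-0 comparisons in control and YC4-R4 libraries, with 25 and 19 such changes, 2 genes met this limit in both, LpxC1 and DIR5, which were picked out after their values were seen; LpxC1 belongs to a group of near-identical copies. Across the 20651 genes, the YC4-R4 effects in the libraries labelled Col-0 and rdd had a Pearson correlation of 0.342 and a Spearman correlation of 0.064. For the rdd effects in control and YC4-R4 libraries these were 0.262 and 0.265. These correlations run across genes, which are not independent replicates, and the compared effects share no libraries. Over genes with an average log2 CPM of 5 or more, an alternative with fewer genes, the first correlation was 0.190.

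**Figure D2:**
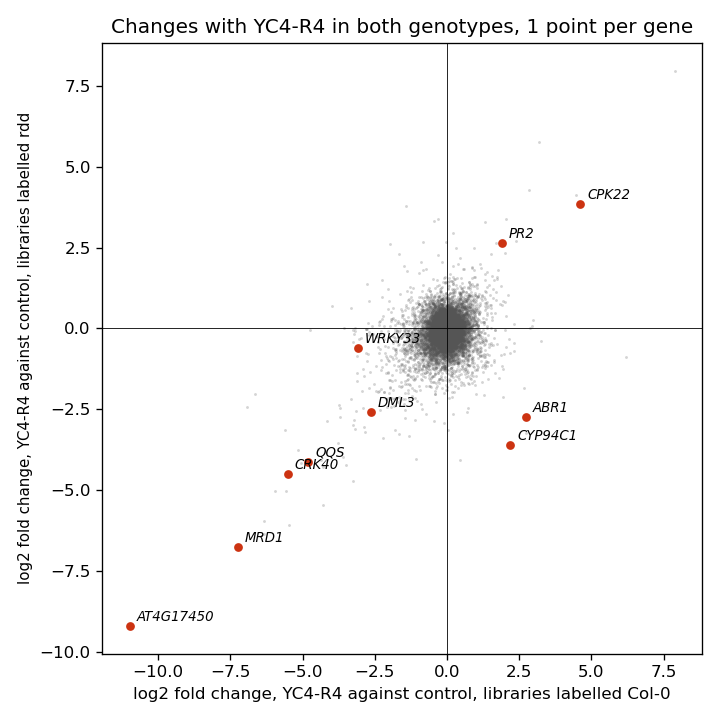
Log2 fold change with YC4-R4 in the libraries labelled Col-0 (horizontal axis) against that in the libraries labelled rdd (vertical axis), 1 point per tested gene, with named genes in red; positions of genes at or near 0 counts, such as AT4G17450, depend on the prior count. MRD1 and CRK40 lie low on both axes, while CYP94C1 lies at 2.2 and -3.61.

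In control libraries, ERD5 and MIOX2 were higher and CBF2 and WRKY70 lower in those labelled rdd than in those labelled Col-0. ERD5, which encodes a proline dehydrogenase, rose from 73.2 ± 1.16 to 575 ± 2.77 CPM (log2 2.97 ± 0.04). MIOX2, an oxygenase that opens myo-inositol, rose from 13.1 ± 1.36 to 86.2 ± 3.75 CPM (2.72 ± 0.07). MIOX1 of the same family stood at 14.6 ± 0.68 and 14.9 ± 1.54 CPM. CBF2, a transcription factor of cold acclimation, fell from 19.4 ± 1.45 to 1.99 ± 0.48 CPM (-3.26 ± 0.16), and WRKY70 from 218 ± 2.43 to 39.4 ± 4.91 CPM (-2.46 ± 0.06). The genes with the highest fold changes also included AT2G38240 (3.84 ± 0.29), the DnaJ-domain gene AT1G72416 (3.33 ± 0.05), the abscisic acid receptor gene PYL6 (3.28 ± 0.13), GAT1_2.1 (3.15 ± 0.22) and ABR1 (2.94 ± 0.20). Those with the lowest included AT2G15020 (-3.93 ± 0.18), the AP2/ERF-type gene AT1G33760 (-3.40 ± 0.13), AT1G72920 (-3.27 ± 0.11), MYB77 (-3.02 ± 0.06), the expansin gene EXPA8 (-2.97 ± 0.09) and the calcium-binding protein gene AT4G27280 (-2.91 ± 0.06). Apart from MIOX1, which was not called, the highest adjusted p among these genes was 1.5e-13, for AT2G38240 (edgeR, Benjamini-Hochberg). AT5G41761 was higher by 2.66 ± 0.30, and by 3.28 without Col-0 control replicate 3. GAT1_2.1 and ABR1 overlap another tested gene, and AT1G72920 has a similar neighbour, AT1G72910 (-2.91 ± 0.08).

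All 40 photosynthesis genes were lower in the control libraries labelled rdd, also adjusted over the list alone, with a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 2.0e-15; adjusted p = 0.0696 with an estimated correlation). LHCB3 was at -0.65 ± 0.04. Root markers moved the other way: 13 of 18 were higher and 1 lower, or 14 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00176, and 0.0512 with an estimated correlation). MRN1 was at 0.96 ± 0.17 and THAD1 at 0.54 ± 0.08, while PYK10, the most abundant of these markers, fell by 0.28 ± 0.03. Morning clock genes were lower in 4 and higher in 0 of 5 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00196; adjusted p = 0.0744 with an estimated correlation). CCA1 was at -1.44 ± 0.08. Salicylic acid genes were lower in 15 and higher in 3 of 30 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00861; adjusted p = 0.0559 with an estimated correlation). CBP60G was at -2.15 ± 0.07 and SARD1 at -2.10 ± 0.10. Pattern-triggered immunity genes were lower in 10 and higher in 7 of 21 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0350; adjusted p = 0.173 with an estimated correlation). WRKY33 fell by 2.48 ± 0.07 and RBOHD by 1.5 ± 0.05, whereas FLS2 rose by 1.70 ± 0.06. In the touch and wounding list, 10 of 12 genes were lower and 2 higher, with a median of -1.44 (camera p = 3.8e-08, not adjusted for other lists; p = 0.0312 with an estimated correlation). The libraries labelled Col-0 control, part of this comparison, are those that stood apart for WRKY33 and WRKY70. Abscisic acid, drought and cold genes were lower in 13 and higher in 4 of 21 cases, or 14 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00318; adjusted p = 0.0559 with an estimated correlation). The proline synthesis gene P5CS1 was at -1.34 ± 0.04 and COR47 at 0.70 ± 0.04. Aliphatic glucosinolate genes were lower in 13 and higher in 1 of 15 cases, or 14 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 6.6e-06; adjusted p = 0.0194 with an estimated correlation). The regulator MYB29 was at -1.36 ± 0.10 and CYP79F1 at -0.73 ± 0.04.

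The jasmonate-ethylene list was higher in 8 and lower in 1 of 12 cases in the same libraries, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00196; adjusted p = 0.0512 with an estimated correlation). The regulator ORA59 rose by 2.13 ± 0.17 and EBF2 by 1.28 ± 0.04, while the ethylene synthesis gene ACS6 fell by 2.73 ± 0.07. Jasmonate genes were lower in 13 and higher in 8 of 29 cases, or 13 and 9 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.447). CYP94C1 was at 2.46 ± 0.08 and LOX4 at -1.78 ± 0.05. Heat shock genes were lower in 6 and higher in 0 of 9 cases, or 7 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00176; adjusted p = 0.0536 with an estimated correlation). HSP90.1 was at -0.88 ± 0.06. Sulfur deficiency genes were lower in 8 and higher in 0 of 13 cases, or 9 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00176; adjusted p = 0.0559 with an estimated correlation). LSU2 was at -1.81 ± 0.13. Cell wall expansion genes were lower in 7 and higher in 3 of 11 cases, or 8 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0267; adjusted p = 0.0744 with an estimated correlation). TCH4 was at -1.41 ± 0.04 and XTH4 at 0.52 ± 0.04. Over all genes, 4319 were higher and 4743 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05), with a median absolute log2 fold change of 0.37, and 1046 of them differed 2-fold or more, 474 higher and 572 lower.

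In YC4-R4 libraries, genes of the jasmonate list were lower in those labelled rdd than in those labelled Col-0. CYP94B3, which hydroxylates jasmonoyl-isoleucine, stood at 0.888 ± 0.254 CPM in rdd against 16.1 ± 0.78 CPM in Col-0 (log2 -4.20 ± 0.15). CYP94C1 (-3.34 ± 0.09), the repressor gene JAZ7 (-3.34 ± 0.14) and CYP94B1 (-3.23 ± 0.18) were lower too. The lowest fold changes also included RAS1, named for its response to abscisic acid and salt (-4.85 ± 0.22; -5.44 without rdd YC4-R4 replicate 2), AT2G17660 (-4.41 ± 0.28), AT1G22810 (-3.70 ± 0.33), the AP2/ERF-type gene DDF1 (-3.66 ± 0.24) and PHI1 (-3.18 ± 0.07). The highest were smaller: AT1G35210 (1.96 ± 0.25), the PQ-loop protein gene AT4G36850 (1.73 ± 0.09), the MATE transporter gene AT3G23550 (1.62 ± 0.16), AT5G41761 (1.58 ± 0.24), PCR1 (1.46 ± 0.13) and the glucosyltransferase gene UGT85A4 (1.41 ± 0.08). The highest adjusted p among these genes was 2.2e-06, for AT5G41761 (edgeR, Benjamini-Hochberg). AT2G17660, AT1G22810, AT3G23550 and UGT85A4 overlap another tested gene.

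Of 29 jasmonate genes, 23 were lower and 1 higher in the YC4-R4 libraries labelled rdd, also adjusted over the list alone, with a median of -0.78 (camera, Benjamini-Hochberg adjusted p = 4.7e-20; adjusted p = 4.3e-04 with an estimated correlation). Among them were LOX4 (-2.68 ± 0.06), LOX3 (-2.26 ± 0.05) and OPR3 (-1.44 ± 0.04). Aliphatic glucosinolate genes were lower in 14 and higher in 0 of 15 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.7e-14; adjusted p = 4.3e-04 with an estimated correlation). FMOGS-OX1 was at -1.31 ± 0.07 and SOT17 at -1.14 ± 0.05. Abscisic acid, drought and cold genes were lower in 13 and higher in 2 of 21 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.2e-06; adjusted p = 0.0109 with an estimated correlation). RD29A was at -1.76 ± 0.05 and the dehydrin gene ERD10 at -1.57 ± 0.04. Pattern-triggered immunity genes were lower in 10 and higher in 2 of 21 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00134; adjusted p = 0.106 with an estimated correlation). RBOHD was at -0.87 ± 0.05. Photosynthesis genes were lower in 23 and higher in 4 of 40 cases, or 24 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00134; adjusted p = 0.400 with an estimated correlation). LHCB2.2 was at -0.60 ± 0.04 and LHCB4.3 at 0.64 ± 0.06. Root markers were higher in 1 and lower in 2 of 18 cases, or 1 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.856). Evening clock genes were lower in 5 and higher in 0 of 6 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0131; adjusted p = 0.160 with an estimated correlation). GI was at -0.93 ± 0.06.

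In the same comparison, sulfur deficiency genes were lower in 7 and higher in 1 of 13 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0165; adjusted p = 0.111 with an estimated correlation). APR1 was at -0.65 ± 0.04. Heat shock genes were lower in 3 and higher in 0 of 9 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0165; adjusted p = 0.106 with an estimated correlation). HSP90.1 was at -1.07 ± 0.07. Flavonoid genes were higher in 4 and lower in 1 of 14 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0342; adjusted p = 0.106 with an estimated correlation). DFR was at 0.78 ± 0.17 and the anthocyanin regulator PAP1 at -1.63 ± 0.30; the list's call was lost without rdd YC4-R4 replicate 1 (0.0700), with a range of 0.0265 to 0.106 over the camera alternatives and 9.0e-04 by fry, against no change. Salicylic acid genes were higher in 4 and lower in 5 of 30 cases, or 4 and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.673). ACD6 was at 0.96 ± 0.04 and PAD4 at -0.76 ± 0.09. Over all genes, 2956 were higher and 2979 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05), with a median absolute log2 fold change of 0.31. Of these, 401 differed 2-fold or more, 90 higher and 311 lower, or 400 in all with groups at 0 counts set to the floor of 3.

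By the interaction test, in which a positive value means a higher YC4-R4 effect in the libraries labelled rdd, jasmonate genes were lower as a list. Pattern-triggered immunity genes went both ways and were not called as a list. For CYP94C1 the difference was -5.81 ± 0.12, from 4 group means of 8.97 ± 0.44, 41.2 ± 1.18, 49.5 ± 3.28 and 4.03 ± 0.60 CPM in Col-0 control, Col-0 YC4-R4, rdd control and rdd YC4-R4. WRKY33 (2.46 ± 0.11) and WRKY70 (2.52 ± 0.09) differed in the other direction, while WRKY18 (-3.02 ± 0.07) did not. WRKY70 stood at 218 ± 2.43 CPM in Col-0 control and at 46.1 ± 1.02, 39.4 ± 4.91 and 48.3 ± 4.89 CPM in the other groups. The lowest values also included AT2G38240 (-6.03 ± 0.37), ABR1 (-5.49 ± 0.28), CYP94B1 (-4.52 ± 0.27), AT1G72416 (-3.33 ± 0.07) and PYL6 (-3.19 ± 0.18). The highest included AT1G35210 (4.69 ± 0.28), AT2G15020 (4.58 ± 0.25), AT1G72920 (3.95 ± 0.18), the cold-response factor genes CBF1 (3.57 ± 0.41) and CBF2 (3.21 ± 0.30), EXPA8 (3.54 ± 0.14) and PBP1 (3.11 ± 0.22). The highest adjusted p among these genes was 8.2e-09, for CBF1 (edgeR, Benjamini-Hochberg). AT5G36790, again resting on rdd YC4-R4 replicate 2, was at 3.5 ± 0.71 and at 1.73 without it. CBF1 and CBF2 are similar neighbours, and ABR1, WRKY33 and PBP1 overlap another annotated gene.

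**Figure D3:**
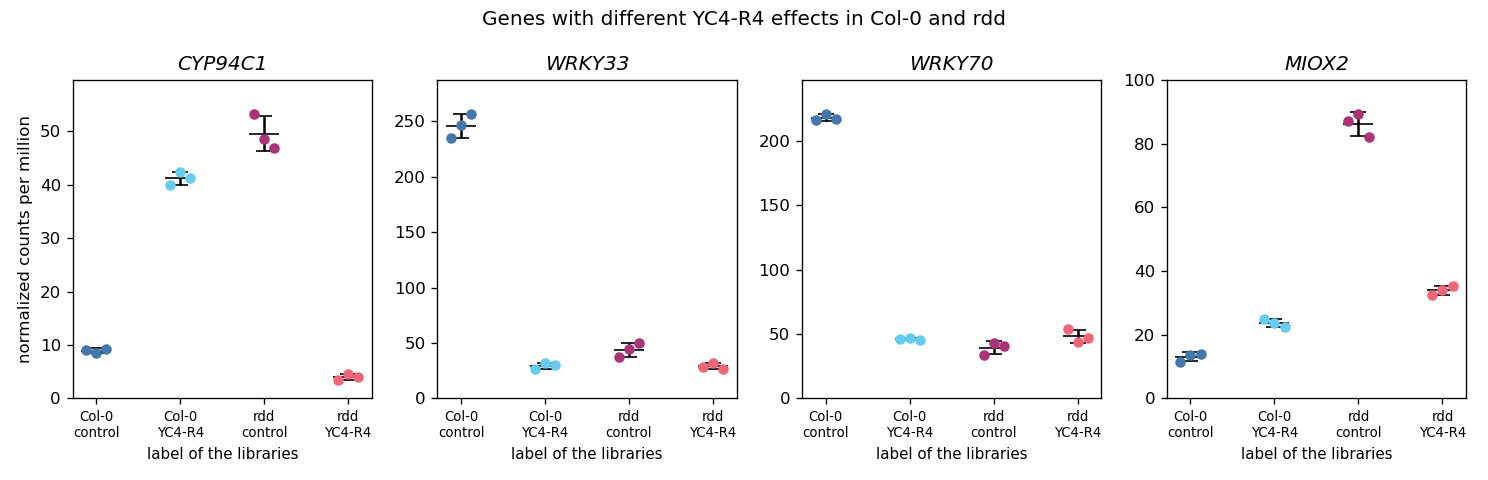
Normalized CPM of CYP94C1, WRKY33, WRKY70 and MIOX2 (vertical axis, from 0) in each of the 12 libraries by label (horizontal axis); points are libraries, the horizontal bar is the mean and the whiskers are 1 SD (n = 3). WRKY70 averaged 218 CPM in the libraries labelled Col-0 control and between 39.4 and 48.3 CPM in the other groups.

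Of 29 jasmonate genes, 19 had a lower and 5 a higher YC4-R4 effect in the libraries labelled rdd, or 20 and 5 adjusted over the list alone, with a median difference of -0.91 (camera, Benjamini-Hochberg adjusted p = 1.4e-09; adjusted p = 0.00712 with an estimated correlation). Among them were JAZ6 (-2.14 ± 0.07), LOX3 (-1.86 ± 0.07) and OPR3 (-1.54 ± 0.06). Photosynthesis genes had a higher effect in 32 and a lower one in 0 of 40 cases, or 35 and 0 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.4e-09; adjusted p = 0.148 with an estimated correlation). RCA was at 0.52 ± 0.05. Root markers moved against them, lower in 8 and higher in 1 of 18 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00626; adjusted p = 0.0584 with an estimated correlation). MRN1 was at -1.35 ± 0.24 and PYK10 at 0.19 ± 0.04. The 5 morning clock genes were higher, also adjusted over the list alone, with a median of 1.13 (camera, Benjamini-Hochberg adjusted p = 1.8e-04; adjusted p = 0.0584 with an estimated correlation). LHY was at 1.47 ± 0.13. Median log2 values of the photosynthesis and morning clock lists were -0.31 and -0.78 with YC4-R4 in Col-0. For rdd against Col-0 in control libraries they were -0.36 and -1.08. They were -0.099 and 0.38 with YC4-R4 in rdd, and -0.13 and 0.052 for rdd against Col-0 in YC4-R4 libraries. The larger shifts of both lists were thus in the comparisons that hold the Col-0 control libraries. Salicylic acid genes were higher in 11 and lower in 2 of 30 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0143; adjusted p = 0.0679 with an estimated correlation). CBP60G was at 1.93 ± 0.11 and SARD1 at 1.92 ± 0.15. The touch and wounding list moved the same way, with 8 of 12 genes higher and 2 lower and a median of 1.3 (camera p = 1.97e-04, not adjusted for other lists; p = 0.116 with an estimated correlation). Pattern-triggered immunity genes were higher in 10 and lower in 6 of 21 cases, or 10 and 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.642). MYB51 was at 1.45 ± 0.11 and FLS2 at -2.18 ± 0.08. Flavonoid genes were higher in 7 and lower in 0 of 14 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00281; adjusted p = 0.0584 with an estimated correlation). CHS was at 1.2 ± 0.10. Cell wall expansion genes were higher in 7 and lower in 3 of 11 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00979; adjusted p = 0.0584 with an estimated correlation). EXPA3 was at 1.35 ± 0.11 and TCH4 at -0.86 ± 0.05.

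Aliphatic glucosinolate genes had a lower YC4-R4 effect in rdd in 7 and a higher one in 3 of 15 cases, or 10 and 3 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00979; adjusted p = 0.0584 with an estimated correlation). SOT17 was at -0.58 ± 0.07. Jasmonate-ethylene genes were lower in 7 and higher in 2 of 12 cases, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0440; adjusted p = 0.105 with an estimated correlation). EBF2 was at -1.24 ± 0.05 and ACS6 at 2.75 ± 0.11. The list's call was lost with the replicate block (0.0545) and without any of 6 libraries, Col-0 control replicate 1 (0.0553), Col-0 YC4-R4 replicate 2 (0.0518), rdd control replicate 2 or 3 (0.0573 and 0.0559) and rdd YC4-R4 replicate 2 or 3 (0.105 and 0.0603), with a range of 0.0235 to 0.105 over the camera alternatives and 1.8e-05 by fry, against no change. In all, 3339 genes had a higher and 2980 a lower YC4-R4 effect in the libraries labelled rdd (edgeR, Benjamini-Hochberg adjusted p under 0.05), with a median absolute log2 difference of 0.46. The interaction keeps its value and calls if the labels of the Col-0 YC4-R4 and rdd control libraries are exchanged, while the pairwise comparisons do not. None of them can be run without those groups and still use both genotypes and treatments.

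Genes of myo-inositol, a sugar alcohol named in the series title, were called as a list in 1 of the 5 comparisons, rdd against Col-0 in YC4-R4 libraries, and this call was lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0307; adjusted p = 0.106 with an estimated correlation). If the labels of the Col-0 YC4-R4 and rdd control libraries were exchanged, that comparison would be YC4-R4 against control in rdd. In control libraries, MIPS1, the main synthase of the pathway, stood at 185 ± 5.50 CPM in Col-0 and 106 ± 3.3 CPM in rdd (log2 -0.80 ± 0.04). In YC4-R4 libraries it was lower in rdd by 0.55 ± 0.04 as log2. With YC4-R4 it fell by 0.26 ± 0.04 in the libraries labelled Col-0 and was at -0.01 ± 0.04 in those labelled rdd, an interaction of 0.25 ± 0.06 (edgeR, Benjamini-Hochberg adjusted p = 8.0e-07, 0.879 and 4.5e-04). MIOX2 rose with YC4-R4 in Col-0 (0.87 ± 0.08) and fell in rdd (-1.34 ± 0.06), an interaction of -2.21 ± 0.10 (edgeR, Benjamini-Hochberg adjusted p = 1.6e-11, 1.8e-20 and 5.8e-20). MIPS2 was higher with YC4-R4 in both, by 0.27 ± 0.08 and 0.32 ± 0.08 (edgeR, Benjamini-Hochberg adjusted p = 0.00687 and 0.00283); the first call was lost without Col-0 YC4-R4 replicate 3 (0.0706), with a range of 0.00531 to 0.0706 over the alternatives. MIPS3 was at -0.08 ± 0.06 in Col-0 and fell by 0.37 ± 0.06 in rdd (edgeR, Benjamini-Hochberg adjusted p = 0.297 and 3.7e-06); MIPS2 and MIPS3 overlap another tested gene. Of the 24 tested genes of the list, 12 were lower and 6 higher in rdd than Col-0 control libraries, or 12 and 7 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.346). In YC4-R4 libraries 10 were lower and 2 higher, or 11 and 2 adjusted over the list alone. The list's call was also lost without rdd YC4-R4 replicate 3 (0.0526), with a range of 0.0145 to 0.106 over the camera alternatives and 3.6e-05 by fry, against no change. With YC4-R4, 6 were higher and 1 lower in Col-0, also adjusted over the list alone, and 4 higher and 5 lower in rdd, or 5 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.211 and 0.911).

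Several lists were not called by camera in any of the 5 comparisons. The DNA methylation and demethylation machinery had adjusted p between 0.381 and 0.842 (camera, Benjamini-Hochberg). In control libraries 7 of its 35 genes were higher and 2 lower in rdd, or 5 and 2 adjusted over the list alone. Camalexin genes had adjusted p between 0.0683 and 0.475 (camera, Benjamini-Hochberg), with 2 higher and 4 lower of 8 in that comparison, or 3 and 4 adjusted over the list alone. Auxin response genes (0.116 to 0.697) had 5 higher and 4 lower of 17, also adjusted over the list alone. Iron deficiency genes (0.0980 to 0.854) had 5 higher and 12 lower of 23, or 5 and 13 adjusted over the list alone. Phosphate starvation genes (0.138 to 0.707) had 1 higher and 3 lower of 13, and senescence genes (0.063 to 0.980) 3 higher and 4 lower of 12, both also adjusted over the list alone. Of the 8 floral organ markers 2 were expressed enough to be tested, and the list was not tested. Median, mean and test had 1 sign in each of the 46 called list results. They differed in sign in 18 of the 69 others, such as the methylation-sensitive loci with YC4-R4 in Col-0 (median 0.30, mean -1.25, test lower).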

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

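Of the tests in this part, those of large shared changes, of correct labels, of the time of day and of the root share were chosen after the results they bear on were seen. The results listed first are those in which the YC4-R4 effect differed between the libraries labelled rdd and Col-0 by the interaction test (edgeR for genes, camera for lists). Positive values mean a higher effect in rdd.

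The interaction called 6319 genes. Of 100 splits of the libraries, the real one included, 1 gave as many, the real one, and the highest other count was 1059. These splits mixed all 4 groups, so they ask whether the groups differ in any way. They cannot decide on the interaction alone. For the pairwise comparisons, 10 splits are too few for a share under 0.05. Their real counts were 6145 (YC4-R4 in Col-0), 6652 (YC4-R4 in rdd), 9062 (rdd in control) and 5935 (rdd in YC4-R4), and the highest of the other splits gave 0, 1, 0 and 0.

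By list, the median differences were -0.91 for jasmonate, -0.47 for jasmonate-ethylene defence, -0.29 for aliphatic glucosinolates and -0.49 for root markers. With an estimated correlation the jasmonate call held (camera, Benjamini-Hochberg adjusted p = 0.00712), and the others were lost (adjusted p = 0.105, 0.0584 and 0.0584). Medians were 0.063 for salicylic acid, 0.27 for photosynthesis, 0.69 for cell wall expansion, 0.62 for flavonoids and 1.13 for the morning clock. These calls were lost with an estimated correlation as well (adjusted p = 0.0679, 0.148, 0.0584, 0.0584 and 0.0584 in that order). Genes with the highest log2 differences were AT1G35210 (4.69), AT2G15020 (4.58), AT1G72920 (3.95), CBF1 (3.57), EXPA8 (3.54), AT5G36790 (3.5, and 1.73 without rdd YC4-R4 replicate 2), AT1G78410 (3.25), AT1G72910 (3.22), CBF2 (3.21) and PBP1 (3.11). Those with the lowest were AT2G38240 (-6.03), CYP94C1 (-5.81), ABR1 (-5.49), CYP94B1 (-4.52), AT1G72416 (-3.33), PYL6 (-3.19), RAS1 (-3.17, and -3.76 without rdd YC4-R4 replicate 2), AT5G05600 (-3.07), WRKY18 (-3.02) and RLP33 (-2.98).

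Within hormone and immune lists, log2 differences were -2.14 for JAZ6, -1.86 for LOX3, -1.54 for OPR3, 2.75 for ACS6, -1.24 for EBF2, 0.63 for HEL and -0.50 for ERS1. WRKY70 was at 2.52, WRKY33 at 2.46, CBP60G at 1.93, SARD1 at 1.92, WRKY53 at 1.65, MYB51 at 1.45, PHI1 at -1.88 and FLS2 at -2.18. In metabolism, MIOX2 was at -2.21, GOLS3 at -2.47, MIOX1 at -0.52, MIPS1 at 0.25, CHS at 1.2, F3H at 1.09, CHI at 1.02, FLS1 at 0.99, SOT17 at -0.58, MAM3 at -0.56, BCAT4 at -0.53 and CYP79F1 at -0.41. GOLS3 rested on few counts, 25 and 60 over the Col-0 control and YC4-R4 libraries and 23 and 11 over those labelled rdd. Among cell wall and clock genes, EXPA3 was at 1.35, TCH4 at -0.86, XTH9 at -0.67, PRR9 at 2.59, LHY at 1.47, RVE8 at 1.13 and CCA1 at 0.80. Among photosynthesis and root genes, LHCB4.3 was at 0.82, RBCS1B at 0.57, RCA at 0.52, LHCB1.4 at 0.52, PYK10 at 0.19, MRN1 at -1.35, THAD1 at -0.63 and THAH at -0.35. The THAH call was lost without Col-0 YC4-R4 replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0536, in a range of 0.00295 to 0.0536 over the alternatives).

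DML2 and DML3 counts followed the treatment labels and not the genotype labels, which an exchange of the labels of the Col-0 YC4-R4 and rdd control libraries could give. Shared changes leave an exchange open. In both YC4-R4 comparisons 26 genes changed 8-fold or more in 1 direction, 4 higher and 22 lower, against 2 in both rdd comparisons. AT4G17450, for example, had 764 and 746 counts in the control groups and 0 and 1 in the YC4-R4 groups. An exchange could give this, and so could a YC4-R4 effect shared by both genotypes. Directions over all genes called in both were added as a measure after that count was seen. For YC4-R4, 1504 of 3139 were opposite (981 for independent lists), and for rdd 1011 of 3772 (1302 for independent lists). Spearman correlations were 0.064 and 0.265. An exchange alone does not set the share of opposite directions, so that share decides nothing. Other tests decided nothing. Of 3 tested loci tied to demethylation, EPF2 had the larger same-sign change in the YC4-R4 comparisons (-2.86 and -3.03), 1 locus for an exchange. ALN had it in the rdd comparisons (0.58 and 0.08), by sign only, as the second value was not called. The rule took size and equal sign and ignored the direction of change. A rise of ALN in rdd is therefore no evidence that the labels are right, and 1 locus of 3 cannot decide. Genes changed 2-fold or more in both YC4-R4 comparisons lay within 1 Mb of the mutated genes in 14 of 182 cases (one-sided Fisher's exact p = 0.365). For the rdd comparisons it was 5 of 120 (one-sided Fisher's exact p = 0.920). Correct labels, with YC4-R4 lowering both transcripts and alleles that leave their counts, cannot be told apart from an exchange by DML3 in rdd against Col-0 control libraries (-0.50), since both allow a change under 2-fold there. If labels were exchanged, what is given here as YC4-R4 against control may be a genotype comparison and the reverse, while the interaction would stand.

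The jasmonate list was lower in the interaction. Handling just before harvest that moves both lists alike would lower the rapid touch and wounding list as well. Its median was 1.3 (range -1.39 to 2.72, camera p = 1.97e-04, p = 0.116 with an estimated correlation), which argues against handling of that kind only. The touch list was lower with YC4-R4 in Col-0 (11 lower and 0 higher of 12, median -1.95). In rdd against Col-0 control libraries it was lower too (10 lower and 2 higher, median -1.44). Both comparisons hold the libraries labelled Col-0 control, so handling that raised the list there remains open. A difference in the time of day at harvest may contribute and cannot be told apart: the morning clock list was called with a median of 1.13 (adjusted p = 0.0584 with an estimated correlation), while the evening list had a median of -0.15 and was not called (camera, Benjamini-Hochberg adjusted p = 0.259). Harvest times are not given in the sources used here. An effect of genotype on the response remains open, and the interaction cannot tell it apart from a difference in harvest or handling.

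In rdd against Col-0 control libraries, root markers were higher and photosynthesis genes lower, calls that were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0512 and 0.0696). A larger root share in the harvested plants, acting alone, would raise markers found only in roots alike. The 18 markers differed among themselves by more than their errors, with a Cochran's Q of 299.2 and 17 degrees of freedom. Of these, 13 were higher, while PYK10, the most abundant, was lower (-0.28). PYK10 had the smallest standard error (0.032), so it weighs most in Q, and it overlaps another tested gene. These values argue against a larger root share that acts alone and alike on all markers, in a test that leans on PYK10. They leave a larger root share open as part of the cause, since markers also expressed in shoots would rise by less. A change within roots by genotype remains open and untested.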

How the results depend on the processing

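No test in this part was chosen after the results were seen. Counts of called genes stayed within 1.5 times the reported ones except with the 2-fold threshold, lower by its construction. It left 682 genes for YC4-R4 in Col-0, 658 for YC4-R4 in rdd, 1046 for rdd in control, 401 for rdd in YC4-R4 and 936 for the interaction, of which 204, 178, 474, 90 and 417 were higher. In the same order, DESeq2 called 4971, 5441, 7702, 4771 and 5099 genes. Leaving out each library in turn gave 5065 to 5323, 5711 to 6600, 8052 to 8218, 4908 to 5967 and 5649 to 6357 genes. The highest counts for YC4-R4 in rdd, rdd in YC4-R4 and the interaction came without rdd YC4-R4 replicate 2. A fit to 6 libraries has no interaction.

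The replicate numbers did not pair the libraries: deviations from group means correlated between -0.0434 and 0.0223 for equal numbers and between -0.0379 and 0.0342 for other numbers. With the replicate number as a block, 6034, 6512, 8976, 5821 and 6197 genes were called, the correlation of the YC4-R4 effects was 0.343, and 44 list results and 5 results for the mutated genes were called. The calls lost were DML3 in rdd against Col-0 control, salicylic acid with YC4-R4 in Col-0 and jasmonate-ethylene defence in the interaction, and no other call of a named gene or list changed.

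The correlation of the YC4-R4 effects was 0.380 over genes called in either comparison and 0.190 over genes with an average log2 CPM of 5 or more, and the cause was not tested. It ran from 0.335 to 0.359 without 1 library. Of 115 list results, camera called 46, and 11 with an estimated correlation. With fry, which does not compare a list with other genes, 82 were called. Without 1 library, 43 to 49 were called, and 11 of the 46 were called in each alternative tried for them. Of 307 called results for named genes, 300 were called in each alternative tried for them. For genes these were DESeq2, RLE factors, the replicate block and leaving out each library, and not the other alternatives. Most of these genes were named for a large fold change or a small adjusted p, so kept calls were likely from the start. The mutated genes gave 6 calls, 5 with DESeq2 and 5 to 6 without 1 library. No result reversed.

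Depth and 3 libraries per group limit small changes: in the simulated data a 1.2-fold change was recovered in 48% of cases for YC4-R4 in Col-0 and 20% for the interaction. Fewer genes changed in the simulation than were called here, and all groups had the same spread, so the real shares may differ.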

Other observations

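The touch list tested here was written after the counts were at hand and before its values were seen, and the other genes in this part were picked out after theirs were seen. The list's 12 genes include calcium-binding protein genes such as TCH2 and TCH3 and regulators such as ZAT10 and ZAT12. Its values with YC4-R4 ranged from -3.05 to -0.29 in the libraries labelled Col-0 and from -1.79 to 0.071 in those labelled rdd. Between rdd and Col-0 in YC4-R4 libraries, 6 of the 12 genes were lower and 5 higher, with a median of -0.045 (camera p = 0.107, p = 0.467 with an estimated correlation). These p-values were not adjusted for the other lists.

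The libraries labelled Col-0 control stood apart for further regulators. Their mean was 163 CPM for ACS6 against 23.7 to 24.4 CPM in the other groups, 118 against 12.1 to 14.9 CPM for MYB77 and 19.4 against 1.99 to 2.13 CPM for CBF2. On the first principal component of log2 CPM, with 34.1% of the variance, these libraries lay at -42.6 to -40.9 and the others at 5.11 to 27.2.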
